A study of Mus musculus with 4 samples.

How the data were processed

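The series measured RNA in female germline stem cells with 2 control and 2 spermidine libraries after 4 h. Per the labels' protocols, total RNA was treated with DNase, mRNA was isolated and paired-end Illumina libraries were made. The protocols name a pair of library kits, and the labels give no batch. Per the submitters' processing notes, HISAT2, DESeq2 and the genome build mm9 were used, with no roles or versions. The counting program and its settings are not given in the sources used here.

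The deposited table holds whole-number counts, not normalised, for 106519 RefSeq transcript rows with exon positions, per the file headers. Of these rows, 86040 (80.8%) matched a gene symbol in a RefSeq gene table of the GRCm38 assembly. Of the matched rows, 88.5% lay inside their gene's GRCm38 span, so the positions are given as GRCm38 and not as mm9. Rows of a gene were summed, giving 53291 features, of which 32812 had a symbol. Unmatched rows were kept as their own features and held 1.72%, 1.63%, 4.45% and 1.13% of counts in control replicates 1 and 2 and spermidine replicates 1 and 2.

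The 49254 rows with no base of their own held at most 0.001% of the counts of any library, and 721 rows with bases of their own on 1 strand only held at most 0.001%. Reads overlapping several rows were therefore left out without regard to strand. Genes whose transcript rows share nearly all their bases are nearly invisible, and 32.2% of genes with a symbol had under 300 bases of their own. Other genes with several rows are counted on their own bases only. Of the 7836 tested genes, 5471 had a single row. A gene without counts here is not shown to be silent.

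Genes were kept with edgeR's filterByExpr by group (count minimum 10, total minimum 15), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with the group as the only term and 2 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. TMM factors were 0.961, 0.973, 1.30 and 0.824 in the order above. Log2 CPM used a prior count of 2. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Adjustment was over the 30 lists with at least 5 tested genes. Fold bounds use a floor of 3 counts over a group, and genes with 1 to 3 counts in a group have a ratio with a 95% counting interval. In list medians at the bound, a group with 0 to 3 counts was set to 3, and no value exceeded the fitted one. A floor of 3 counts is 0.416 and 0.421 CPM in the controls and 3.81 and 1.75 CPM in the spermidine libraries.

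The procedure was tested on simulated counts for the 7836 genes of this comparison, with 200 genes changed. It recovered 10.2% of 88 genes changed 4-fold and 62% of 92 genes changed 16-fold, and called 5 unchanged genes. In a simulation without changes it called 1 gene. The simulation raised and lowered genes in equal numbers, unlike the data, where 1943 of 2256 calls were higher. It also gave each gene 1 dispersion for both groups. In the data, the SD across genes of the log2 ratio between replicates was 0.804 for control and 1.87 for spermidine. The simulation therefore does not show the error rate under such an imbalance or such unequal spread.

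The tests, 31 gene lists, alternatives and rule for named genes were set before the data were examined. The rule takes the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 and both spermidine libraries on the same side of both controls, and the 4 smallest p in each direction. It adds the 2 smallest p of each list on autophagy, lysosome, polyamines, mTOR, apoptosis and germline, the top called member of each other list, and 8 fixed genes: Sqstm1, Map1lc3b, Becn1, Ulk1, Odc1, Sat1, Ddx4 and Ifitm3. Predicted genes without a symbol beyond a Gm or Rik name were passed over in the parts on size and p. A gene that this rule takes is not reported here. Other members are given as examples of their list and were chosen after their values were seen.

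Alternatives covered scaling (RLE, upper-quartile, library totals), the low-count filter, DESeq2 1.42.0, limma-voom, the legacy edgeR test, a replicate block, thresholds and each library left out. Fits that left out a library tested the genes that passed the filter with all 4 libraries. Alternatives added after the data were seen used the deposited transcript rows, protein-coding genes without AY036118, genes with a single row, controls thinned to 1253272 counts (the mean spermidine total), all libraries thinned to 554572 counts without AY036118, counts with the background on receptor genes subtracted, and robust edgeR. Between the replicates of a group, chi-square over degrees of freedom was 40.8 for control and 32.2 for spermidine, so neither pair is a duplicate. The median log2 fold change of all tested genes was 0.23 with TMM and 0.37 with upper-quartile factors, and list medians can be read against it. The tables were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.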

Results

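Poly(A) RNA sequencing was used to profile female germline stem cells of C57BL/6 mice, a long-passaged cell line with germ cell properties derived from ovary, after 4 h with or without spermidine. Spermidine is a polyamine, a small cation made from ornithine and studied as an inducer of autophagy, the lysosomal breakdown of cell contents. Each group had 2 libraries, and the dose is not given in the sources used here. The comparison asks which transcripts differ after spermidine, with autophagy as the subject named by the series. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

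The control libraries held 7206176 and 7128901 counts, and the spermidine libraries 787600 and 1718944. The row AY036118 took 1.68% (95% exact Clopper-Pearson interval 1.67 to 1.69) and 1.64% (1.63 to 1.65) of control counts, against 29.6% (29.5 to 29.7) and 30.7% (30.6 to 30.8) of spermidine counts. Its first exon, on the minus strand of chromosome 17 from 39847647 to 39848826 (GRCm38), lies inside an annotated ribosomal RNA gene. Intervals and floors given here cover counting error only. Counts appeared on 855 of 1292 olfactory and vomeronasal receptor gene models in spermidine replicate 1, on 123 in spermidine replicate 2, and on 24 and 63 in the controls. The noncoding RNA Xist, made from the inactive X chromosome of female cells, had 5 and 2 counts in the controls and 114 and 588 in the spermidine libraries. Log2 CPM correlated across genes at 0.969 between the controls and 0.732 between the spermidine libraries, and at 0.594 to 0.649 between groups. The first principal component held 74.1% of the variance and separated the groups, and the second, with 22%, separated the spermidine libraries from each other.

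**Figure D1:**
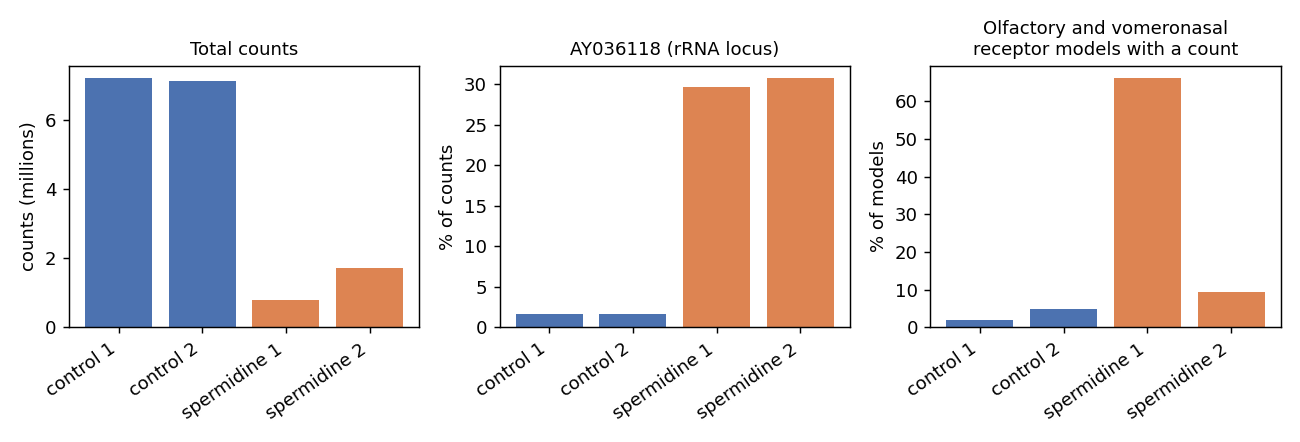
Bars give, for each of the 4 libraries, total counts, the percent of counts on AY036118 and the percent of 1292 receptor gene models with at least 1 count. The spermidine libraries have the lower totals (787600 and 1718944) and the larger AY036118 shares (29.6% and 30.7%), and spermidine replicate 1 has counts on 66.2% of receptor models.

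Among the gene lists, the highest medians with all 4 libraries were those of oocyte and granulosa and theca genes, many of which had few counts in the control libraries and more in both spermidine libraries. Wt1 and Foxl2, transcription factors of granulosa cells, Zp1, a protein of the egg coat, and Krt8, an epithelial keratin, were among the genes that rose. Genes that fell included the transferrin receptor Tfrc with 2053 and 1240 control counts against 13 and 21, the leukocyte and platelet protein Plek (log2 fold change -3.91 ± 0.65 SE), the fetal serum protein Afp (-3.92 ± 0.69) and Ccne1, the cyclin of S phase entry (-3.38 ± 0.61). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2256 of 7836 tested genes differed, 1943 higher and 313 lower in spermidine, each by at least 2-fold. Of the genes called higher, 412 had 0 counts in both controls. Autophagy genes as a group were not called, and Map1lc3b, the precursor of the autophagosome marker LC3, had a log2 fold change of 0.40 ± 0.56 (adjusted p = 0.627). Of 7836 tested genes, 5187 had both spermidine libraries on the same side of both controls, and 2255 of the called genes did. The number of calls was 484 without spermidine replicate 1, 3725 without spermidine replicate 2, 0 without control replicate 1 (1926 at an unadjusted p under 0.05) and 1513 without control replicate 2, where the lone library was assumed to vary like the other group. It was 0 by edgeR with no low-count filter (4255 at an unadjusted p under 0.05), 275 with at least 1 CPM asked of all libraries, 1056 with controls thinned to the mean spermidine total, 804 with all libraries thinned to 554572 counts without AY036118, and 1491 with the receptor background subtracted, against 2194 by DESeq2 and 1954 by limma-voom in the main setting.

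Genes of granulosa and theca cells, the hormone-producing cells around the oocyte, were higher for 10 of 11 tested members, and for 10 with p adjusted over the list alone. The list's median log2 fold change was 8.56, or 8.43 with low-count members at their bound (camera adjusted p = 0.00041, and adjusted p = 0.71 with an estimated correlation). That median was 6.015 without spermidine replicate 2 and 9.356 without spermidine replicate 1. Wt1 had 2 and 1 control counts against 51 and 330, a pooled ratio of 769.5 (95% counting interval 261.3 to 3748). Foxl2 rose by 9.18 on the log2 scale, the inhibin subunit genes Inha and Inhbb by 8.58 and 9.44, and Star, which brings cholesterol into mitochondria for steroid synthesis, by 5.60. Among meiosis and oocyte genes, 10 of 11 were higher, also over the list alone, with a median of 8.94, or 8.15 at the bound (camera adjusted p = 0.00041, and adjusted p = 0.745 with an estimated correlation). Their median was 6.30 without spermidine replicate 2 and 9.85 without spermidine replicate 1. The egg coat gene Zp1 had a pooled ratio of 1179 (324.1 to 9766), Zp3 rose by 9.52, and Padi6, needed for the oocyte's cytoplasmic lattices, by 8.94. Counts of these genes were unequal between the spermidine libraries: Zp3 had 30 and 751, and Inhbb 135 and 5498. Most granulosa and theca genes and all oocyte genes called higher passed the low-count filter only through the spermidine libraries. The filter thus favoured a rise, and the shares and medians are not independent support. With no filter the medians were 6.62 and 6.75, against 3.56 for all tested genes. With at least 1 CPM asked of all libraries neither list had enough tested members for camera. Xist, chosen after its values were seen, rose with these groups by 9.01 ± 0.98 (adjusted p = 0.00281, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Rn7sk, another noncoding RNA chosen in that way, rose by 4.46 ± 0.96, from unequal control counts of 3326 and 549 to 4743 and 9786. Small noncoding RNAs as a class held 0.182% and 0.0513% of control counts and 1.90% and 1.41% of spermidine counts. The value of Rn7sk therefore need not reflect its expression, and the cause was not tested. Protein-coding genes held 95.1% and 95.3% of control counts and 56.0% and 65.2% of spermidine counts. These totals include AY036118, with 29.6% and 30.7% of spermidine counts. Most of the gap is therefore the AY036118 share and not a separate difference.

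Ovarian surface epithelium markers were higher for 7 of 8 tested members, also over the list alone, with a median of 7.96, or 6.51 at the bound (adjusted p = 0.00163, and adjusted p = 0.71 with an estimated correlation). Krt8 had 1 and 2 control counts against 41 and 148, a pooled ratio of 381.7 (128.6 to 1868). All 4 tested endothelial markers were higher, too few for camera, among them the receptors Tie1 (7.16 ± 0.91) and Flt1 (5.54). The epithelium and endothelial genes called higher also passed the low-count filter only through the spermidine libraries. With no filter the epithelium median was 5.68, against 3.56 for all tested genes. Fibroblast and stroma markers were higher for 11 and lower for 1 of 17, or 13 and 1 over the list alone (median 4.41, adjusted p = 0.00041, and adjusted p = 0.745 with an estimated correlation). The proteoglycan gene Lum rose by 7.91 ± 0.91 and the collagen gene Col3a1 by 7.11, while Vim, an intermediate filament gene, fell by 2.05. Extracellular matrix genes were higher for 6 and lower for 2 of 13 without a call for the list (adjusted p = 0.193, and 0.0346 without control replicate 2). With at least 1 CPM asked of all libraries the list was called (0.0193), with 5 of 11 genes higher and 0 lower. Timp3, a protease inhibitor, rose by 6.14 ± 0.65, and Tgfb1 fell by 2.64. Over the 4 fits that left out a library, list medians were 6.015 to 9.356 for granulosa and 6.30 to 9.85 for oocyte genes. They were 7.325 to 8.536 for epithelium and 3.73 to 5.83 for stroma genes. Those fits kept the genes that passed the filter with all 4 libraries. The left-out library therefore still helped choose the members, and these medians are no independent check. Single calls did not hold in each of these fits. Without spermidine replicate 1 the genes called higher numbered 8 for granulosa, 6 for oocyte, 4 for epithelium and 6 for stroma, and with the background subtracted 6 of 7 tested oocyte genes were.

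**Figure D2:**
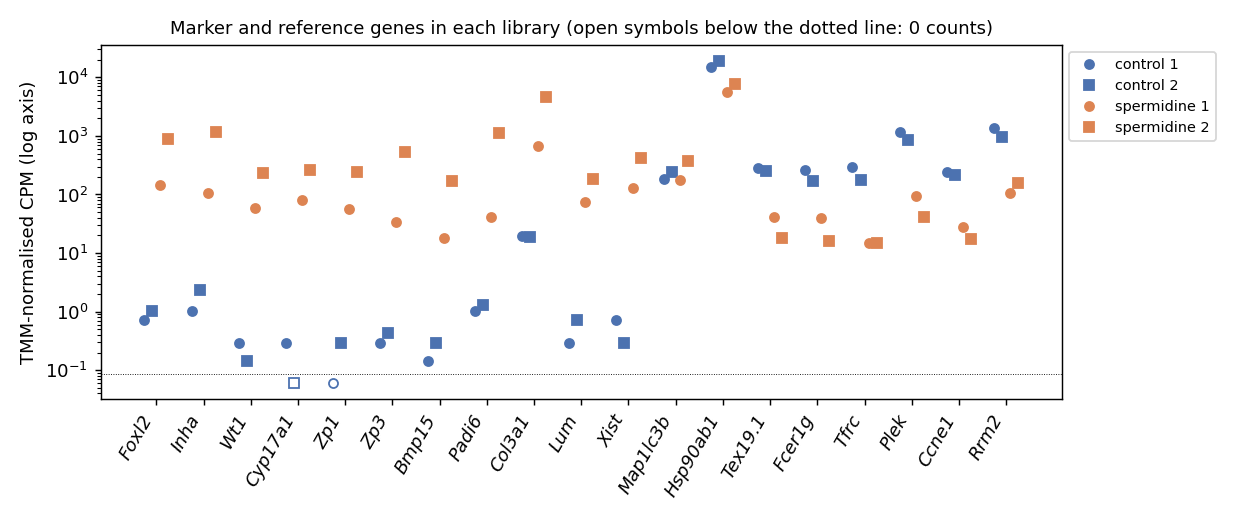
TMM-normalised CPM on a log axis for 19 genes chosen after their values were seen, with a symbol per library (circles, replicate 1, and squares, replicate 2). Open symbols below the dotted line stand for 0 counts. Ovarian genes such as Foxl2 (5 and 7 control counts, 127 and 1257 spermidine counts) lie higher in both spermidine libraries, and Plek and Tfrc lie lower.

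Of germline and germline stem cell genes, 7 of 11 were higher and 1 lower, the same numbers over the list alone (median 5.21, camera adjusted p = 0.0946, and 0.0401 without control replicate 1). Without spermidine replicate 1, 3 were higher and 1 lower, and without control replicate 2, 5 and 1. Dppa3, a maternal chromatin factor, rose by 8.02 ± 1.38, the tetraspanin gene Cd9 by 5.21 ± 0.86 and Ifitm3 by 2.83 ± 0.68. Tex19.1, a germ cell gene that restrains transposons, fell by 3.25 with 1955 and 1770 control counts against 36 and 25. Ddx4, the germ cell helicase also called Vasa, was not tested, with 1 count in all 4 libraries together. Pluripotency genes were higher for 6 of 10, or 7 over the list alone (median 8.33, or 5.92 at the bound, adjusted p = 0.0129, and adjusted p = 0.71 with an estimated correlation). Only 1 was higher without spermidine replicate 1 (list adjusted p = 0.0488), and 4 of 8 tested with the background subtracted, where the median was 5.42. Mycn rose by 7.93 ± 1.43, and Pou5f1 had 0 and 0 control counts against 2 and 42. The pluripotency genes called higher passed the low-count filter only through the spermidine libraries. With no filter the list's median was 5.96, against 3.56 for all tested genes. Counts for Dppa3 were 9 in spermidine replicate 1 and 263 in replicate 2, the library with the higher Xist count.

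Of 15 tested genes of the autophagy machinery, Epg5, a tether for autophagosome fusion, was higher (3.77 ± 1.02, adjusted p = 0.0207 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and none was lower, and no member passed over the list alone. Epg5 had 7 and 1 counts in the controls and 7 and 12 in the spermidine libraries. In the alternatives where it was tested, its log2 fold change lay between 2.98 and 5.56. With 3007 bases of its own, its 7 counts in spermidine replicate 1 are not above the receptor background there, 3.15 counts per kb. By Benjamini-Hochberg adjusted p its call was lost with DESeq2 (0.0831), edgeR's legacy test (0.0539), no filter (0.309), and without spermidine replicate 1 (0.0767), control replicate 1 (0.0804) or control replicate 2 (0.192), and it held with the other scalings and limma-voom. Epg5 had too few counts to be tested with controls thinned to the mean spermidine total, with the receptor background subtracted or at equal depth without AY036118. Other members of the list were not called in the first 2 of these, 2 of 10 were higher at equal depth, and 2 were higher and 1 lower without spermidine replicate 2. The list's median was 0.26 against 0.23 for all tested genes, and its mean was 0.60 against 1.29. Camera placed it lower than other genes (adjusted p = 0.926). That direction is not stable: it was higher with upper-quartile factors, library totals, thinned controls, the background subtracted, equal depth (adjusted p = 0.337), protein-coding genes alone, 1 CPM in all libraries and without spermidine replicate 1, never with a call. With no low-count filter, where 26 of 31 lists were called, this one was called lower (camera adjusted p = 0.0204). The median was -0.18 without spermidine replicate 2 and 0.61 without replicate 1. Wipi1, a phosphoinositide-binding autophagy protein, had 1.67 ± 0.74 (adjusted p = 0.131 by the same edgeR test with Benjamini-Hochberg adjustment), and was called at equal depth without AY036118 (2.92 ± 0.76, adjusted p = 0.0299). It was 0.11 ± 0.61 without spermidine replicate 2 and 2.37 ± 0.33 without replicate 1, so the value of Wipi1 rests on replicate 2. No member of the 6 tested selective autophagy receptor and mitophagy genes was called, over all genes or over the list alone (median 0.57, camera adjusted p = 0.91, direction lower). Calcoco1 had 2.15 ± 0.77 and the mitophagy kinase gene Pink1 1.54 ± 0.58, and 1 or 2 members passed under the other scalings. At equal depth without AY036118 both were called, with 2.79 ± 0.62 and 1.93 ± 0.45, but without spermidine replicate 2 neither was, with 0.98 ± 0.60 and 0.94 ± 0.47. Sqstm1, which encodes the receptor p62 and has 114 bases not shared with another row, had -0.79 ± 0.98 (edgeR, Benjamini-Hochberg adjusted p = 0.588). Without spermidine replicate 2, the values of Sqstm1 and Map1lc3b changed sign, to 0.10 ± 0.94 and -0.18 ± 0.45. Becn1 and Ulk1, which start autophagosome formation, were not tested: Becn1 had 3 and 2 control counts and 0 in spermidine, and Ulk1 had 2 counts, both in spermidine replicate 1. These counts do not show expression, because reads shared between transcript rows were left out, and only 25 of the 43 autophagy genes had at least 300 bases of their own.

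Lysosome genes were higher for 4 of 27 and lower for 0, or 3 and 0 over the list alone (median -0.27, mean 0.55, adjusted p = 0.59, direction lower). The cathepsin gene Ctsf had 1 and 2 control counts against 49 and 151, a pooled ratio of 404 (136.3 to 1975), and Gpnmb, a glycoprotein of endosomes, rose by 6.59 ± 0.94. Of 11 polyamine genes, 3 were higher and 2 lower, also over the list alone (median -0.34, mean 0.53, adjusted p = 0.51, direction lower). The arginase gene Arg2 rose by 5.76 ± 1.06, and Arg1 had a pooled ratio of 38.4 (11.3 to 202.5). Srm, which encodes spermidine synthase, fell by 2.45, and Eif5a2, a translation factor modified with spermidine, fell by 2.80. Odc1 and Sat1, the enzymes that start polyamine synthesis and breakdown, had 1 and 8 counts in all and were not tested. In the PI3K, AKT and mTOR list 3 of 20 genes were higher and 0 lower, also over the list alone (median -0.10, mean 0.68, adjusted p = 0.662, direction lower), and its median turned to 0.05 with upper-quartile factors. The insulin receptor substrate gene Irs1 rose by 6.01 ± 0.89. Apoptosis genes were higher for 5 and lower for 2 of 19, also over the list alone (median 0.60, mean 1.24, adjusted p = 0.926, direction lower). The pro-apoptotic genes Bok and Bcl2l11 rose by 7.03 ± 1.38 and 5.10 ± 1.06, and Bcl2, which opposes apoptosis, fell by 2.45. Counts were unequal between the spermidine libraries. Bok had 3 and 13 control counts against 13 and 406, and Bcl2l11 had 6 and 7 against 51 and 17. A response to spermidine was not told apart from a difference in cell source for these genes. Without spermidine replicate 2 the calls were 5 higher and 6 lower for lysosome genes, 3 and 4 for polyamine genes, 4 and 2 for the PI3K list and 7 and 4 for apoptosis genes, and without spermidine replicate 1 they were 2 and 0, 1 and 0, 0 and 0, and 1 and 1. Camera's direction also depended on the setting, never with a call except lower with no filter for each list: for lysosome genes it was higher with 1 CPM in all libraries, thinned controls (median 0.28), the background subtracted and equal depth (median 0.50), and it turned in some settings for the PI3K and apoptosis lists too.

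Genes of growth and the cell cycle were placed lower than other genes by camera, and with all 4 libraries few of them were called singly. G1/S and replication genes were lower for 3 of 18, or 2 over the list alone (median -1.30, adjusted p = 0.00139, and adjusted p = 0.745 with an estimated correlation), and Rrm2, a ribonucleotide reductase subunit, fell by 3.18. Of 29 ribosomal protein genes only Rps2 was called, and none over the list alone (median -0.74, adjusted p = 0.00041, and adjusted p = 0.745 with an estimated correlation). Rps2 fell by 2.96 ± 0.70. Glycolysis and hypoxia genes were lower for 2 and higher for 1 of 19, also over the list alone (median -1.53, adjusted p = 0.000971, and adjusted p = 0.71 with an estimated correlation). Pgk1 fell by 2.14, while Aldoa, with 2 and 1 control counts, had a pooled ratio of 74.7 (23.7 to 378.9). Nuclear genes of the respiratory chain were lower for 2 of 27 and for 0 over the list alone (median -0.68, adjusted p = 0.00146, and adjusted p = 0.745 with an estimated correlation), and Cycs, cytochrome c, fell by 2.30 ± 0.55. With upper-quartile factors and library totals, 6 and 8 G1/S genes were lower. For G2/M genes no member of 11 was called, against 2 and 5 under those scalings (median -1.15, adjusted p = 0.0129, and adjusted p = 0.745 with an estimated correlation). Single calls depended on the spermidine library: without replicate 2, 13 of 18 G1/S, 8 of 11 G2/M, 18 of 27 respiratory chain and 23 of 29 ribosomal protein genes were lower (medians -1.63, -1.93, -1.70 and -1.69). Without spermidine replicate 1 none of the ribosomal and respiratory chain genes was. There the camera adjusted p was 0.202 for the ribosomal and respiratory chain lists and 0.103 for G2/M genes, so those calls ended. The ribosomal and respiratory chain calls also ended at equal depth without AY036118 (0.0581 and 0.0677) and the G2/M call with the background subtracted (0.0527), while the G1/S and glycolysis lists held in each leave-one-out fit.

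NRF2 and oxidative stress genes were higher for 5 and lower for 3 of 28, or 6 and 7 over the list alone (median -1.13, adjusted p = 0.0234, and adjusted p = 0.745 with an estimated correlation). The glutathione transferase gene Gstm2 rose by 8.54 ± 1.19 and Srxn1, a sulfiredoxin, fell by 2.97. Unfolded protein response genes were lower for 2 of 16 and for 0 over the list alone (median -0.80, adjusted p = 0.0186, and adjusted p = 0.745 with an estimated correlation), and Sdf2l1 fell by 2.05 ± 0.54. ATF4 targets were lower for 2 of 20, also over the list alone (median -0.88, adjusted p = 0.0236, and adjusted p = 0.745 with an estimated correlation), and Phgdh, the entry enzyme of serine synthesis, fell by 2.36 ± 0.57. Without spermidine replicate 2, 12 NRF2 genes were lower and 5 higher, and 8 of 16 unfolded protein response genes were lower (list medians -1.49 and -1.54). The NRF2 and unfolded protein calls ended without spermidine replicate 1 (adjusted p = 0.213 for each), the NRF2 call also without control replicate 1 (0.0572), and the ATF4 call without spermidine replicate 2 (0.475) or control replicate 2 (0.183). All 3 also ended with controls thinned to the mean spermidine total (NRF2 0.084, unfolded protein 0.162, ATF4 0.0635), at equal depth without AY036118 (0.222, 0.222 and 0.18), and with the background subtracted (0.127, 0.135 and 0.11). With 1 CPM in all libraries the unfolded protein (0.195) and ATF4 (0.428) calls ended, and with single-row genes the ATF4 call did (0.0788).

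The other lists were not called by camera. Heat shock genes were higher for 2 and lower for 1 of 17 (adjusted p = 0.0644), with Hspb1 rising by 5.32 ± 1.14, and passed camera with library totals alone (adjusted p = 0.044), without spermidine replicate 2 (0.0118, with 2 higher and 7 lower) and without control replicate 1 (0.048). Immediate early genes were higher for 2 and lower for 1 of 19 (adjusted p = 0.567), with the matricellular gene Ccn2 rising by 5.45 ± 0.87. Of 16 NF-kB genes 1, Lcn2, was higher, by 4.13 ± 0.87 (adjusted p = 0.377), against 4 without spermidine replicate 2 (median 0.75) and 0 without spermidine replicate 1 (median -2.17). Interferon genes were higher for 2 and lower for 1 of 11 (adjusted p = 0.749), or 4 and 1 without spermidine replicate 2, and Ifit1, an antiviral RNA-binding protein, rose by 5.21 ± 0.65. Of 15 p53 targets 2 were higher and 1 lower (adjusted p = 0.567), with the antiproliferative gene Btg2 rising by 5.39 ± 1.16. Cholesterol synthesis genes were lower for 2 of 16 (adjusted p = 0.148), among them Idi1 (-2.16 ± 0.69), and 0 passed over the list alone. None of 13 mitochondrially encoded transcripts (adjusted p = 0.239) and none of 7 replication-dependent histone genes (adjusted p = 0.567) was called. Without spermidine replicate 2, 5 of the 7 histone genes were higher (median 3.49), and cholesterol genes were lower for 6 and higher for 4. Macrophage and leukocyte markers were higher for 2 and lower for 1 of 6, or 2 and 2 over the list alone (adjusted p = 0.533): Lyz2, lysozyme, rose by 4.43 ± 0.67, and Fcer1g, an Fc receptor chain, fell from 1799 and 1186 control counts to 35 and 23 spermidine counts. Camera's direction was lower for the NF-kB, p53 and macrophage lists, which have negative medians and positive means, and for the immediate early list, whose median and mean are positive. Over the list alone, the counts were the same as over all genes in the heat shock, immediate early, NF-kB, interferon and p53 lists.

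**Figure D3:**
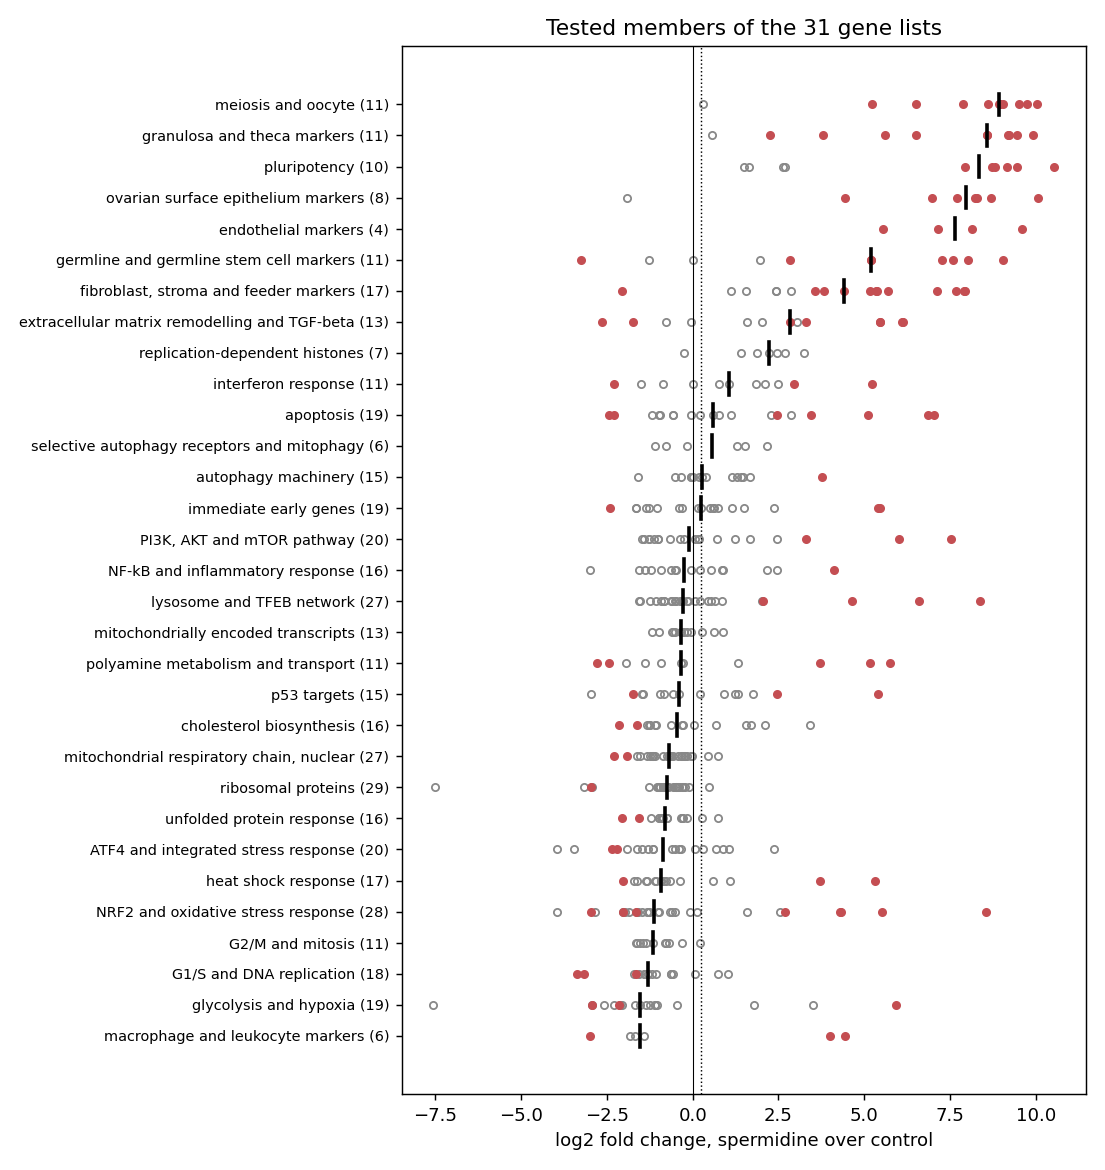
Each point is a tested member of a gene list, placed by its log2 fold change of spermidine over control, filled where its adjusted p was under 0.05 and open otherwise, with the number of tested members in parentheses. Black bars are list medians as fitted, the solid line is 0 and the dotted line is the median of all tested genes (0.23). Granulosa and theca markers have a median of 8.56 and autophagy genes 0.26.

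Among genes named for the size of the change, AF366264 (chromosome 8, 13835229 to 13838089) had 0 and 0 control counts against 237 and 181, at least 844.3-fold higher with a floor of 3 counts over the control group. On the same floor Bcl2l10, a BCL-2 family gene (chromosome 9, 75347758 to 75351640), was at least 474.7-fold higher, and Hpgd, which inactivates prostaglandins, at least 399.9-fold. Bmp6, a growth factor gene, was at least 276.7-fold higher, the collagen gene Col6a5 at least 252.5-fold and the calcium channel gene Cacna1e at least 240.4-fold. These bounds pool unequal spermidine libraries. Counts in replicates 1 and 2 were 18 and 217 for Bcl2l10, 6 and 192 for Hpgd, and 115 and 4 for Cacna1e. They were 51 and 86 for Bmp6 and 70 and 55 for Col6a5. The receptor background of spermidine replicate 1, 3.15 counts per kb, was not taken off these bounds. Cacna1e has 14045 bases of its own and Col6a5 9297, so part of their replicate 1 counts can be background. Hpgd has 1719, so its 6 replicate 1 counts are about the background and its bound rests on replicate 2. The bound of Cacna1e rests on replicate 1, the library with the background. The values are therefore bounds on pooled counts and not on expression above background. Aldh1a1, a retinoic acid synthesis enzyme, had the smallest p and rose by 9.53 ± 0.84, from 0.651 ± 0.511 to 503.5 ± 139.6 CPM (SD, n = 2). Wnt4, a signalling ligand of ovary development, had a pooled ratio of 718 (196.6 to 5964). In the other direction Kir3dl1 was at least 15.9-fold lower with 166 and 123 control counts, and the small nucleolar RNA Snord12 at least 7.54-fold lower with 79 and 58. Both are uncertain, because Kir3dl1 has 279 bases of its own and Snord12 is 66 bases long. The call of Snord12 was also lost with upper-quartile factors, library totals, no filter, the replicate block, single-row genes, thinned controls and the background subtracted, and without spermidine replicate 1 or control replicate 1. St6galnac4, Tespa1 and Tasp1 had pooled ratios of 0.0197 (0.000497 to 0.11), 0.0201 (0.000508 to 0.113) and 0.0239 (0.00493 to 0.0703). Prnp, the prion protein gene (chromosome 2, 131909928 to 131938436), fell by 4.19 ± 0.78. Without spermidine replicate 1, where calls were fewer, only Aldh1a1 and Wnt4 of the genes in this paragraph were still called. Each coordinate is the span of a gene's exons in the deposited table, on GRCm38.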

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

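The tests here on transcript rows, protein-coding genes, single-row genes, thinned libraries, subtracted background and robust edgeR were chosen after the data were seen, and the others before. The main setting called 2256 genes (1943 higher, 313 lower), each at least 2-fold, and 13 lists. Counts of genes stayed within 1.5 times of these with RLE or upper-quartile factors, library totals, DESeq2, limma-voom and the legacy test, as did those of lists where run (not for DESeq2 and the legacy test), and the share called higher ran from 80.8% to 87% across scalings. With no filter, edgeR called 0 genes, 0 higher and 0 lower (4255 at an unadjusted p under 0.05, over 29023 tested), and 26 lists. Asking for 1 CPM in all libraries gave 275 calls, 230 higher and 45 lower, and 8 lists. An adjusted p under 0.01 gave 1282 calls, 1238 higher and 44 lower. With an estimated correlation 0 lists were called, and with fry 1, the ovarian surface epithelium (adjusted p = 0.035). Leaving out a library gave 0 to 3725 calls, at least 2-fold in each case, 0 to 2517 higher, 0 to 1208 lower and 8 to 14 lists. Of the 484 calls without spermidine replicate 1, 478 were also called with all libraries. Controls thinned to the mean spermidine total gave 1056 calls, 953 higher and 103 lower, which left depth over genes other than AY036118 unequal. All libraries thinned to 554572 counts without AY036118, in 1 draw, gave 804 calls, at least 2-fold in each case, 734 higher and 70 lower, 732 of them also called in the main setting, and 7 lists. The subtracted receptor background gave 1491 calls, 1256 higher, and 9 lists, as did thinned controls. The replicate block gave 1775 calls with 94 lower, called the germline list (adjusted p = 0.0221) and lost the NRF2 list (0.0906). The labels do not say whether the replicate numbers pair the libraries. The correlation of replicate differences across genes was -0.03, which shows no shared pattern but cannot exclude a shared culture or batch. Among named genes, alternatives set beforehand kept the direction and side of the threshold for 545 values, lost the call for 169 and gained it for 5, and added ones did so for 286, 13 and 9. The 2 reversed values, both without spermidine replicate 2, were 0.10 for Sqstm1 and -0.18 for Map1lc3b, in ranges over the left-out libraries of -1.86 to 0.10 and -0.18 to 0.83. The cause of these shifts was not tested, beyond the fewer genes or samples that the filters and left-out libraries bring. At these depths and replicate numbers the simulation, with 1 dispersion per gene for both groups, recovered 10.2% of 4-fold changes.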

Other observations

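The tests of library depth on receptor counts, on ovarian genes and, with controls thinned, on blood cell genes, and the test of cell sources, were chosen after their results were seen, and the limits of the test of a response to spermidine were rewritten after its value was seen. The 4 blood cell lists were written after the data were seen. The other thinning tests, the background test and the test of receptor densities were added after the main results were seen, with their limits set before their own values.

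Of the 4 blood cell lists, camera called the leukocyte and mast cell lists lower in spermidine and did not call the megakaryocyte and erythroid lists. General leukocyte genes were lower for 9 and higher for 2 of 19 tested (median log2 fold change -2.47, or -2.18 at the bound, camera adjusted p = 0.00193, and adjusted p = 0.406 with an estimated correlation). Plek fell by 3.91, Lcp2, an adaptor of immune receptors, by 2.92 from 13868 and 12027 control counts, and Cst7, a leukocyte cystatin, by 4.19. Mast cell and basophil genes were lower for 3 of 6 (median -2.12, adjusted p = 0.0181, and adjusted p = 0.406 with an estimated correlation), among them Cpa3, the mast cell carboxypeptidase, which fell by 3.79. Megakaryocyte and platelet genes were lower for 3 of 5 (adjusted p = 0.075), and the thrombin receptor gene F2r fell by 3.20 from 17435 and 15996 control counts. Erythroid genes went both ways, 3 higher and 1 lower of 5 (adjusted p = 0.235): the globin genes Hba-a1 and Hbb-bs rose, to 63 and 554 and to 85 and 491 spermidine counts from 20 and 28 and from 68 and 29, and Tfrc fell. Hba-a1 and Hbb-bs have near-identical copies, so their counts are uncertain. Fcer1g is in the mast cell list and in the macrophage list fixed earlier.

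Of the 2256 calls 86.1% were higher in spermidine, against 67.6% of 3725 without spermidine replicate 2, 93.4% of 484 without spermidine replicate 1 and 95.5% of 1513 without control replicate 2, so its size depends on the libraries used. With controls thinned to the mean spermidine total 90.2% of calls were higher, and with all libraries thinned to equal depth without AY036118 91.3% were, so the depth difference does not account for the imbalance. After the receptor background was subtracted 84.2% were higher. The subtraction used 1 mean density per library, while receptor counts were uneven over models. It therefore argues only against an evenly spread background as the whole cause and cannot exclude an uneven one. A response to spermidine stays open and was not tested for this imbalance.

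In spermidine replicate 1, counts lay on 66.2% of receptor gene models, at 3.15 counts per kb of own bases against 0.0635 to 0.176 in the other libraries. Receptor CPM was 184.2 times that of the higher control, although this library was the shallowest, which argues against depth. The density over vomeronasal models was 0.89 times that over olfactory models, so both families were covered about alike. The ratio cannot decide the origin, since the families were also close in spermidine replicate 2 (0.203 and 0.164 counts per kb), where the background was low. The counts were not even over models: 4519 lay on 855 of 1292. Reads from genomic DNA or other unspliced sources remain a hypothesis, since DNA was not measured and the protocol names a DNase step. No biological explanation was tested.

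Ovarian genes (22 of granulosa, theca and oocyte lists, median 8.59, or 8.29 at the bound) were higher in spermidine and blood cell genes (35, median -2.18, or -1.99 at the bound, 16 lower and 5 higher) lower by their median, and Xist differed by a pooled ratio of 607.7. Raw counts of 90% of the ovarian genes called higher exceeded both deeper controls in both spermidine libraries. In spermidine replicate 1 the receptor background can also exceed a low control count. It was an expected 26.6% of counts other than AY036118, and Ooep had only 4 counts there. The raw counts therefore do not show ovarian transcripts in both libraries for each gene. With the background subtracted, 9 of 11 granulosa and theca genes and 6 of 7 oocyte genes were higher. The 25 blood cell genes tested with thinned controls had a median of -2.05 (-2.74 with all counts), so depth alone accounts for neither part. At equal depth without AY036118 the 23 tested had -1.82 (-2.76 with all counts), and 22 of the 41 ovarian and blood cell calls were made, against 24 with thinned controls. The gap of 10.77 between the medians (10.28 at the bound), with the Xist difference, is what different cell sources or mixed samples could give. It describes the data and does not test this, since the blood cell lists were written after the data were seen. Most ovarian genes called higher also passed the low-count filter only through the spermidine libraries, so their direction is not independent support. The macrophage and leukocyte list fixed beforehand was not called (camera adjusted p = 0.533). The gap pools unlike libraries: the median log2 ratio of spermidine replicate 2 over replicate 1 was 1.95 for ovarian and -1.26 for blood cell markers. Abundant markers included Star (1302 and 443 spermidine counts), Inhbb (135 and 5498) and Lcp2 (13868 and 12027 control counts). Cell source and a response to spermidine cannot be told apart for these genes, because each goes with the groups. The SD of the log2 ratio between the spermidine libraries over ovarian genes was 2.22, unequal amounts that a graded response could also give. The labels name no sort that would remove other cells. Depth and the AY036118 share also go with the groups and the labels give no batch, so a difference in library preparation cannot be told apart either.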
